A study of Mus musculus with 9 samples.

How the data were processed

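The series holds 9 samples from the epidermis of K14-CreER Tet2 floxed mice. Poly-A selected RNA was sequenced from 40-week-old mice, 3 given vehicle and 3 given tamoxifen, and the design text counts them as 3 and 3, so that the replicates are taken as mice. The 3 libraries of 5-hydroxymethylcytosine pull-down (1 vehicle, 1 tamoxifen and 1 pooled input, from 10-week-old mice) were not analysed here. The labels name no batch and pair no samples, and they include no tamoxifen-treated mice without the recombinase or the floxed alleles, so effects of the drug and of the deletion cannot be separated in this design.

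Per the submitters' processing notes, the authors used Trimmomatic 0.36, STAR 2.5.2b, featureCounts (Subread 1.5.2) and DESeq2, with the genome build GRCm38. The versions of DESeq2 and of the annotation, the strand setting of the counting and the model formula are not given in the sources used here. What was analysed is the authors' deposited table of their comparison, with no values per library. Its first value column is a signal, the mean over all libraries of read counts divided by size factors, per the file headers the base mean of DESeq2, and it is not corrected for gene length. The deposited log2 fold change and its standard error are on the log2 scale. The deposited test score is the Wald statistic of the authors, equal in size to the fold change over its standard error in all 25635 rows (largest gap 2.38e-08) and opposite in sign in all of them. The deposited p-value and adjusted p-value are those of the authors' DESeq2 Wald test, and the adjusted values follow Benjamini and Hochberg. The authors' table lists genes with a mean normalised count from 1.00 upwards.

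Because score and fold change disagree in sign, one of them runs as vehicle over tamoxifen. The fold change was read as tamoxifen over vehicle, since Tet2, the targeted gene, is negative in it. The name of the table puts vehicle first, which matches the score. If this reading were wrong, every direction in the text would turn. Of the 25635 genes, 25444 have a p-value and 17981 an adjusted p-value. DESeq2 as used by the authors leaves the p-value empty where a single library has an extreme count (191 genes) and the adjusted p-value where the mean count is too low (7463 genes, all below a mean of 6.82). Gene symbols came with the authors' table; 472 rows have none, and 25545 identifiers matched the name table used for checking. Gene positions are those of the RefSeq annotation of GRCm38.p6, the same build.

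Depth per library is unknown, and the summed mean normalised count of 40502852 (median gene 71.5) is the only measure of it. Precision is therefore taken from the deposited standard errors. Genes of near-identical families, such as stefins, Sprr2, hair keratins, keratin-associated proteins and globins, share reads in a way that the counting could split, so their single values are uncertain. Opposite-strand neighbours could not be separated, with the strand setting unknown.

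A gene was called at an adjusted p under 0.05 in the authors' deposited table. The adjusted p was recomputed over the same 17981 genes and lay within 0.00283 of the deposited one, which is rounded. The genes named in the text follow a rule fixed before the data were examined: the 3 Tet genes; among called genes with a mean of at least 20 normalised counts, the 12 with the largest rise and the 12 with the largest fall, predicted genes left out; and for each gene list up to 4 called members, or the 1 or 2 with the smallest p. Its further condition, that the libraries of the groups not overlap, could not be applied. Some list members that the rule takes are not reported here. Genes outside the rule, such as Krt10, Lor, Pecam1, Vwf, Krt6a, the hair keratin copies and Gm44829, were chosen after their values were seen.

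The 36 gene lists (656 distinct genes, 643 of them in the table) were fixed before the data were examined. They cover keratinocyte layers, the hair follicle and its glands, cell types that an epidermal preparation could also hold, and signalling and stress responses. Each was tested with cameraPR of limma 3.58.1 (R 4.3.3) on the fold change over its standard error, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 36 lists. This test asks whether the genes of a list stand apart from all other tested genes, it is two-sided, and its p-values are too small where the genes of a list vary together between mice. For each list the number of calls over all genes and the number adjusted over the list alone are given. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Bootstrap intervals (95%) came from 10000 draws of genes, or 2000 for the bins of all genes, and cover the spread between genes, not between mice.

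The design had foreseen an own fit to counts. With the authors' comparison alone that fit could not be made, and the alternatives that need values per library were not run. Alternatives that could be run were an adjusted p threshold of 0.10, a minimum fold, no filter on low counts, a stricter filter at a mean of 40.5 normalised counts (13762 genes) and lists without shared members. Added after the data were seen were filling in the empty p-values, recentring on the median fold change, a preset correlation of 0.1 and a rank form of the list test. The list test was tested on simulated scores for the 17981 genes of the vehicle and tamoxifen comparison. In 100 draws, 2.86% of unchanged lists had an unadjusted p under 0.05, and 94% of draws called a list shifted by 1.5 units of the score. Of 200 single genes shifted by 5 units, 93.5% were recovered and 5.05% of calls were false; the simulated genes were independent of each other.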

Results

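RNA from isolated epidermis was sequenced in mice that carry a tamoxifen-inducible Cre recombinase under the keratin 14 promoter (K14-CreER) and floxed alleles of Tet2, a dioxygenase that oxidises 5-methylcytosine in DNA to 5-hydroxymethylcytosine. The mice were aged to 40 weeks. Of these, 3 received vehicle and 3 received tamoxifen by intraperitoneal injection, at 100 mg/kg daily for 5 days. The epidermis was collected 14 days after the first dose. In the same series, genomic DNA pulled down with an antibody to 5-hydroxymethylcytosine was sequenced from 1 vehicle and 1 tamoxifen sample of 10-week-old mice, with 1 pooled input. Those 3 libraries were not analysed here. The expression values come from the authors' deposited table of the tamoxifen and vehicle comparison, which covers 25635 genes. For each gene it holds a mean normalised read count over the 6 libraries, a log2 fold change with its standard error (SE) and p-values. The mean normalised counts of the authors' deposited table summed to 40502852. The depth of each library is unknown here. The 10 most abundant genes made up 16.7% of that sum in the authors' deposited table, led by mt-Co1 at 3.97%, the spinous keratin Krt10 at 2.98% and the cornified envelope protein gene Lor at 2.10%. Fold changes are given as tamoxifen over vehicle. This direction was read from the negative sign of Tet2 itself, since the test statistic of the table carries the opposite sign to the fold change in all 25635 rows.

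The comparison of vehicle with tamoxifen asks how the epidermal transcriptome differs after tamoxifen, which was given to induce deletion of Tet2. Tet2 (ENSMUSG00000040943, chromosome 3: 133463677-133545136 in GRCm38) had a mean of 661 normalised counts and a log2 fold change of -0.95 ± 0.33 (SE), 1.94-fold lower after tamoxifen, in the authors' deposited table. Its 95% interval, computed from that SE, ran from -1.60 to -0.31. The DESeq2 p of the authors' deposited table was 0.00382 unadjusted and 0.432 adjusted over all genes, so the targeted gene did not pass the threshold. Tet3, with 3907 normalised counts, had a log2 fold change of -0.09 ± 0.35 and Tet1, with 32.7 normalised counts, of -0.26 ± 0.69 in the authors' deposited table. Neither passed there (adjusted p = 1 for both). Since the direction was read from Tet2, its sign is no separate check of the library labels. Reads from exons outside the floxed part of the gene would still count towards Tet2. Its value in each library was not used here.

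At an adjusted p under 0.05, 11 of the 17981 genes with an adjusted p passed in the authors' deposited table, 4 higher and 7 lower after tamoxifen. The 4 that rose included 2 keratins of the inner root sheath, the layer that encases the growing hair. Krt71 (ENSMUSG00000051879, chromosome 15: 101733949-101743097) was 12.7-fold higher, a log2 fold change of 3.66 ± 0.86 (SE, adjusted p = 0.0402) in the authors' deposited table. Krt27 (ENSMUSG00000017588, chromosome 11: 99345565-99351118) was 11.8-fold higher at 3.56 ± 0.84 (adjusted p = 0.0402) in the authors' deposited table. Their means were 26647 and 10211 normalised counts. Cryba4 (ENSMUSG00000066975, chromosome 5: 112246492-112263625), a crystallin gene, had a log2 fold change of 3.45 ± 0.82 (adjusted p = 0.0458) in the authors' deposited table. Gkn3 (ENSMUSG00000030048, chromosome 6: 87383319-87388935), a gastrokine gene, stood at 3.01 ± 0.69 (adjusted p = 0.0346) in the authors' deposited table. Markers of blood vessels and red blood cells also had higher medians after tamoxifen, with log2 fold changes of 2.31 and 1.71.

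The 7 genes that fell included a pair from the stefin A cluster of cysteine protease inhibitors and a gene of the cornified envelope. Cstdc5 (ENSMUSG00000071561, chromosome 16: 36359382-36367570) was 27.9-fold lower, at a log2 fold change of -4.80 ± 1.01 (adjusted p = 0.00946), in the authors' deposited table. Stfa3 (ENSMUSG00000054905, chromosome 16: 36450537-36455392) was 20.5-fold lower, at -4.36 ± 0.91 (adjusted p = 0.00886), in the authors' deposited table. Rptn (repetin, ENSMUSG00000041984, chromosome 3: 93393699-93399442), which encodes a protein of the epidermal cell envelope, fell by 3.95 ± 0.90 on the log2 scale (adjusted p = 0.0344) in the authors' deposited table. The membrane serine protease gene Tmprss11g (ENSMUSG00000079451, chromosome 5: 86485877-86518600) had the smallest adjusted p in the authors' deposited table, 0.00229, with a log2 fold change of -2.98 ± 0.56. The ribonuclease gene Rnase2b (ENSMUSG00000059606, chromosome 14: 51162260-51163018) followed at -2.29 ± 0.47 (adjusted p = 0.00886) in the authors' deposited table. The steroid reductase gene Akr1d1 (ENSMUSG00000038641, chromosome 6: 37529978-37574921), with a mean of 36.0 normalised counts, stood at -4.14 ± 0.94 (adjusted p = 0.0344) in the authors' deposited table. The remaining called gene was the predicted gene Gm44829, at -2.89 ± 0.67 (adjusted p = 0.0393) in the authors' deposited table. Stefin genes are close copies of each other, so the share of reads that each received is uncertain. Whether a single mouse decides any of these falls could not be tested.

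**Figure D1:**
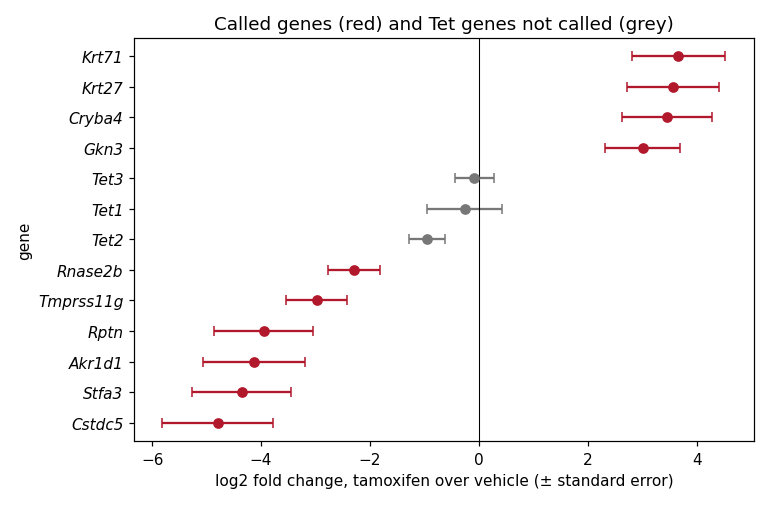
Log2 fold change, tamoxifen over vehicle, of the 10 called genes with an established name (red, adjusted p under 0.05) and of Tet1, Tet2 and Tet3 (grey, not called); points are the deposited estimates and bars 1 standard error. The 4 genes on the right lie between 3.01 and 3.66, the 6 on the left between -4.80 and -2.29, and Tet2 at -0.95.

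Across the 17981 genes with an adjusted p, 874 (4.86%) had an unadjusted p under 0.05 in the authors' deposited table, where 5% or 899 would be expected by chance. Of these, 488 were higher and 386 lower after tamoxifen. The median SE was 0.49, and at that SE a log2 fold change of 2.04 would have been needed for a call. With all fold changes recentred on the median of the tested genes, 0.06, the calls numbered 1 higher and 7 lower instead of 4 and 7, because Krt71, Krt27 and Cryba4 lost their calls (adjusted p = 0.0516 for each). Without the low-count filter the split was 1 higher and 6 lower.

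Genes of the hair shaft and inner root sheath rose together. Of the 36 tested members of this list, 35 had a positive log2 fold change in the authors' deposited table, with a median of 3.02; 2 were called over all genes and 30 when adjusted over the list alone (adjusted p = 1.2e-55 from cameraPR, the test of gene lists run here on the deposited values). Krt71 and Krt27 were the 2 called over all genes. Melanocyte genes, whose products make and carry pigment, had a median log2 fold change of 3.36 over 14 tested members in the authors' deposited table (cameraPR adjusted p = 1.6e-20), with 0 called over all genes and 11 higher when adjusted over the list alone. Tyrp1 stood at 4.10 ± 1.07 (adjusted p over all genes 0.0967) and Tyr, which encodes tyrosinase, at 4.09 ± 1.11 (0.121) in the authors' deposited table. The hair keratins Krt81, Krt83 and Krt86, the pair Krt33a and Krt33b and the keratin-associated proteins are near copies, so values for single members are uncertain. The SEs of hair and melanocyte genes were 2.31 times those of genes with a similar mean count (median ratio), and whether a single mouse decides their rise could not be tested.

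Lists of Hedgehog, Wnt and Notch targets and of proliferation genes were also called higher. All 11 tested Hedgehog targets had positive log2 fold changes, with a median of 0.51 in the authors' deposited table (cameraPR adjusted p = 4.8e-04), 0 called over all genes and 2 adjusted over the list alone, among them Hhip at 2.87 ± 1.06. The 14 Wnt targets had a median of 0.58 in the authors' deposited table (cameraPR adjusted p = 4.8e-04), with 0 called over all genes and 3 adjusted over the list alone. Notum, a secreted Wnt inhibitor, stood at 2.20 ± 0.68 and Wif1 at 2.11 ± 0.69 in the authors' deposited table. Of the 14 Notch targets, 0 were called either way, with a median of 0.34 in the authors' deposited table (cameraPR adjusted p = 0.0167), Hey2 at 2.36 ± 0.93 and Lfng at 1.41 ± 0.58. Proliferation genes had a median of 0.42, with 27 of 28 positive and 0 called either way, in the authors' deposited table (cameraPR adjusted p = 0.00589), and the smallest p values belonged to Stmn1 at 0.56 ± 0.39 and Mcm3 at 0.73 ± 0.52. With a preset correlation of 0.1 between genes in place of 0.01, the Notch (adjusted p = 0.136) and proliferation (adjusted p = 0.151) calls were lost. Follicle stem cell genes were not called, with a median of 0.27 over 18 members in the authors' deposited table (cameraPR adjusted p = 0.163), 0 called either way, Angptl7 at 1.29 ± 0.74 and Cd200 at 0.80 ± 0.48.

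**Figure D2:**
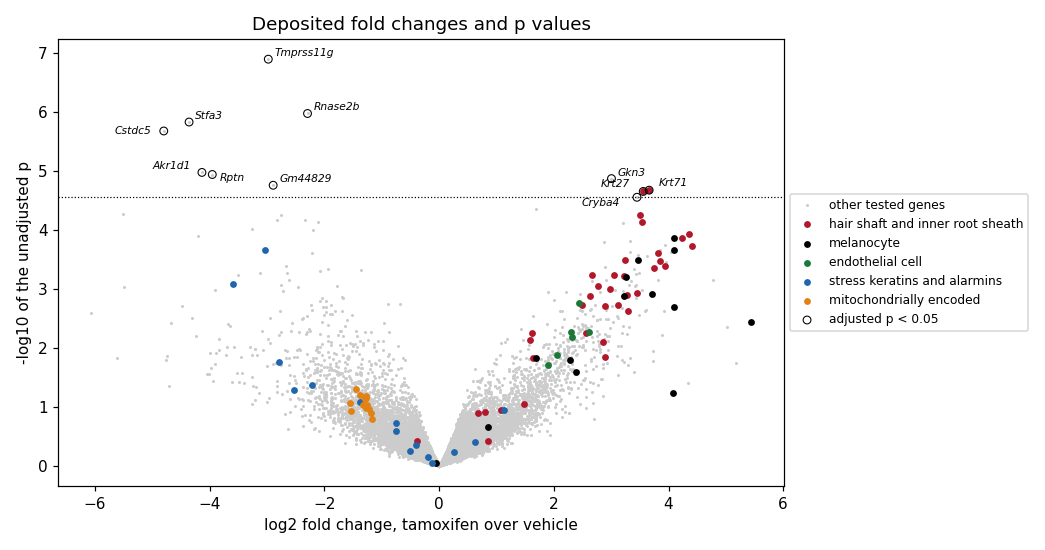
Each point is 1 of the 17981 genes with an adjusted p, with log2 fold change, tamoxifen over vehicle, on the horizontal axis and -log10 of the unadjusted p on the vertical axis; colours mark 5 gene lists, circles the called genes and the dotted line the largest p that was called, 2.8e-05. Hair (red) and melanocyte (black) genes lie far to the right, with medians of 3.02 and 3.36, and mitochondrially encoded genes (orange) form a tight group at a median of -1.28.

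Markers of cells below the epidermis were higher after tamoxifen as well. All 6 tested endothelial genes were positive, with a median log2 fold change of 2.31 in the authors' deposited table (cameraPR adjusted p = 3.4e-10), and 0 were called over all genes but 6 adjusted over the list alone, among them Cldn5 at 2.44 ± 0.78 and Sox17 at 2.31 ± 0.83. A further 9 of the 15 endothelial genes, among them Pecam1 and Vwf, carried a fold change and no p-value. So did 5 of 20 fibroblast and 4 of 18 muscle genes, and all these folds were positive. DESeq2 empties a p-value where a single library has an extreme count. Whether 1 library decides the rise of these lists could not be tested. Erythrocyte genes had a median of 1.71 over 7 members in the authors' deposited table (cameraPR adjusted p = 4.4e-09), with 0 called over all genes and 6 adjusted over the list alone. Slc4a1 stood at 2.67 ± 0.79 and the globin Hbb-bs, a close copy of Hbb-bt, at 2.60 ± 0.92 in the authors' deposited table. All 15 tested dermal fibroblast genes were positive, with a median of 1.26 in the authors' deposited table (cameraPR adjusted p = 7.9e-07) and 0 called either way. Col6a3 stood at 1.91 ± 0.86 and Fbn1 at 1.93 ± 0.90 in the authors' deposited table. Skeletal muscle genes had a median of 1.29 over 14 members in the authors' deposited table (cameraPR adjusted p = 5.9e-06), with 0 called over all genes and 2 adjusted over the list alone, Myh4 at 3.44 ± 1.08 and Myh1 at 2.66 ± 0.98. Schwann cell and nerve genes had a median of 0.56 over 12 members in the authors' deposited table (cameraPR adjusted p = 0.00699), 0 called either way, with Gfra3 at 2.76 ± 1.01; this call was lost at a correlation of 0.1 (adjusted p = 0.0714). Adipocyte genes were not called, with a median of 0.18 over 12 members in the authors' deposited table (cameraPR adjusted p = 0.810), 0 called either way, Adig at -0.97 ± 0.50 and Fabp4 at 1.54 ± 0.84.

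Stress keratins and alarmins, the genes that wounded or inflamed epidermis makes, fell as a group. Of 15 tested members 12 were negative, with a median log2 fold change of -0.75 in the authors' deposited table (cameraPR adjusted p = 1.3e-05), and 0 were called over all genes but 2 lower when adjusted over the list alone. Over all 24 measured members, with those lacking an adjusted p, the median was -1.62 in the authors' deposited table. The members added here had an empty p-value or few counts. All genes with a mean of 1 to 10 normalised counts lay lower in general, at a median of -0.97. The 2 genes were the small proline-rich protein genes Sprr2h at -3.03 ± 0.82 and Sprr1b at -3.59 ± 1.07 in the authors' deposited table. A further 4 members had no p-value, and 3 of them, named after their values were seen, were Krt6b at -5.28 ± 1.21, Krt16 at -3.59 ± 1.04 and Stfa1 at -3.74 ± 1.05 in the authors' deposited table. An empty p-value marks an extreme count in a single library, so 1 library may set these folds. Krt6b shares most of its sequence with Krt6a, which stood at -0.75 ± 0.66 in the authors' deposited table, and the Sprr2 genes are near copies too, so the split of reads between copies is uncertain. The granular and cornified layer list was called lower, with 23 of 30 members negative, a median of -0.34 in the authors' deposited table (cameraPR adjusted p = 4.2e-04) and 1 member, Rptn, called over all genes and over the list alone. Filaggrin (Flg), named after its value was seen, had a log2 fold change of -1.65 ± 0.73 (unadjusted p = 0.0248) in the authors' deposited table. At a correlation of 0.1 the granular call was lost (adjusted p = 0.0664). Melanocyte, endothelial and erythrocyte medians moved the other way at the same time, at 3.36, 2.31 and 1.71.

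Basal, spinous and lipid barrier keratinocyte lists were not called. Basal keratinocyte genes had a median log2 fold change of -0.05 over 16 members (cameraPR adjusted p = 0.527), spinous genes 0.07 over 16 (0.927) and lipid barrier genes 0.02 over 19 (0.571) in the authors' deposited table, with 0 members called either way in each. The members with the smallest p were Itgb1 at 0.97 ± 0.64 and Cd44 at -0.45 ± 0.35 in the basal list, Krt2 at 0.67 ± 0.73 and Krt1 at -0.64 ± 0.71 in the spinous list, and Degs2 at -1.21 ± 1.1 and Aloxe3 at -0.61 ± 0.56 in the lipid barrier list of the authors' deposited table. The TET and DNA methylation enzyme list was not called either, with a median of 0.00 over 20 members in the authors' deposited table (cameraPR adjusted p = 0.463), and 0 called either way. Tet2 had an adjusted p of 0.0764 over the list alone, and Ogt stood at -0.52 ± 0.41 in the authors' deposited table. The sebaceous gland list was called lower, with 16 of 24 members negative and a median of -0.37 in the authors' deposited table (cameraPR adjusted p = 5.1e-05), 0 called over all genes and 3 lower when adjusted over the list alone. These included Awat1 at -1.94 ± 0.55 and Awat2 at -1.61 ± 0.55 in the authors' deposited table, which encode wax ester synthases of sebum. Merkel cell genes were not called, with a median of 0.53 over 8 tested and 0.13 over 10 measured members in the authors' deposited table (cameraPR adjusted p = 0.898, direction lower), 0 called either way, Chga at -1.88 ± 0.71 and Syp at 0.83 ± 0.78.

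Immune cell markers of the epidermis lay lower after tamoxifen. T cell genes had a median log2 fold change of -0.74, with 17 of 21 negative and 0 called either way, in the authors' deposited table (cameraPR adjusted p = 4.5e-07). Both members with the smallest p had few counts in the authors' deposited table. Cd8a, with a mean of 15.2 normalised counts, stood at -2.80 ± 1.02, and Trac, with 16.8, at -1.37 ± 0.62. Langerhans and antigen presenting cell genes had a median of -0.74, with 15 of 16 negative and 0 called either way, in the authors' deposited table (cameraPR adjusted p = 8.0e-04), with Ptprc, the pan-leukocyte gene, at -0.89 ± 0.38 and Mfge8 opposite at 1.41 ± 0.68. The macrophage and granulocyte list was not called, with a median of -0.16 over 16 members in the authors' deposited table (cameraPR adjusted p = 0.667) and 0 called over all genes. Within it the mast cell protease gene Tpsb2 was the 1 member that passed when adjusted over the list alone, at 2.45 ± 0.76, and Mcpt4, another mast cell protease gene, stood at 2.27 ± 0.84 in the authors' deposited table. Interferon response genes had a median of -0.40 over 23 members in the authors' deposited table (cameraPR adjusted p = 0.0153), with Mx1 at -1.70 ± 0.66 and Rsad2 at 1.31 ± 0.64. NF-kB and cytokine genes had a median of -0.44, with 15 of 17 negative, in the authors' deposited table (cameraPR adjusted p = 0.00271), with Cxcl2 at -1.16 ± 0.76 and Il24, below the count limit for an adjusted p, at -4.56 ± 1.69. Neither list had a member called either way, and both calls were lost at a correlation of 0.1 (adjusted p = 0.174 for interferon and 0.0686 for NF-kB). In the same comparison the medians of hair (3.02), melanocyte (3.36), endothelial (2.31) and fibroblast genes (1.26) in the authors' deposited table lay in the opposite direction.

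Mitochondrially encoded genes were called lower as a list. All 13 were negative, and they had a median log2 fold change of -1.28 in the authors' deposited table (cameraPR adjusted p = 4.7e-10), although 0 had an unadjusted p under 0.05 and 0 were called either way. Their quartiles were -1.37 and -1.25 against a median SE of 0.76. Their errors were therefore largely shared, the 13 genes are not separate observations, and the list p-value is too small. The genes with the smallest p were mt-Nd5 at -1.45 ± 0.74 and mt-Co1 at -1.37 ± 0.74 in the authors' deposited table. Mean normalised counts differed widely between them in the authors' deposited table, from 1607762 for mt-Co1 to 186 for mt-Co2, 195 for mt-Atp6 and 218 for mt-Co3, genes named after their values were seen, so what share of their transcripts was counted is uncertain. Immediate early and dissociation stress genes had a median of -0.27, with 20 of 26 negative and 0 called either way, in the authors' deposited table (cameraPR adjusted p = 4.8e-04), Fosl1 at -1.36 ± 0.58 and Nr4a2 at -1.12 ± 0.60. Estrogen and xenobiotic response genes, tested together as a mixed list, had a median of -0.35 over 13 members and 0 called either way in the authors' deposited table (cameraPR adjusted p = 0.0298), with Cyp1a1 at -1.33 ± 0.72 and Tiparp at -0.84 ± 0.48. An estrogen response alone was not tested. At a correlation of 0.1 the immediate early (adjusted p = 0.0638) and the estrogen and xenobiotic (adjusted p = 0.161) calls were lost.

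The remaining 7 lists were not called, and 0 of their members passed over all genes or over the list alone. In the authors' deposited table the medians were 0.18 for p53 targets (cameraPR adjusted p = 0.527), with Bax at 0.41 ± 0.29 and Fas at 0.73 ± 0.52, and 0.10 for EGFR ligands and MAPK feedback (0.525), with Dusp4 at 2.25 ± 0.85 and Hbegf at -1.05 ± 0.49. Mesenchymal transition genes had a median of 0.10 (cameraPR adjusted p = 0.642) in the authors' deposited table, with Mmp13 at -3.83 ± 1.51 and Itga5 at 1.29 ± 0.76. NRF2 targets had a median of 0.05 (cameraPR adjusted p = 0.841), with Ces2g at -0.90 ± 0.49 and Gsr at 0.35 ± 0.38, and cholesterol synthesis genes also 0.05 (0.810), with Mvk at 0.48 ± 0.57, in the authors' deposited table. Circadian clock genes had a median of -0.11 (cameraPR adjusted p = 0.249) in the authors' deposited table, with Clock at -0.41 ± 0.28 and Cry2 at -0.43 ± 0.41. Sex-linked genes had a median of -0.09 over 4 tested Y-linked members (cameraPR adjusted p = 0.527) in the authors' deposited table, with Ddx3y at -0.28 ± 0.24, and Xist, at a mean of 3.1 normalised counts, was below the limit for an adjusted p.

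**Figure D3:**
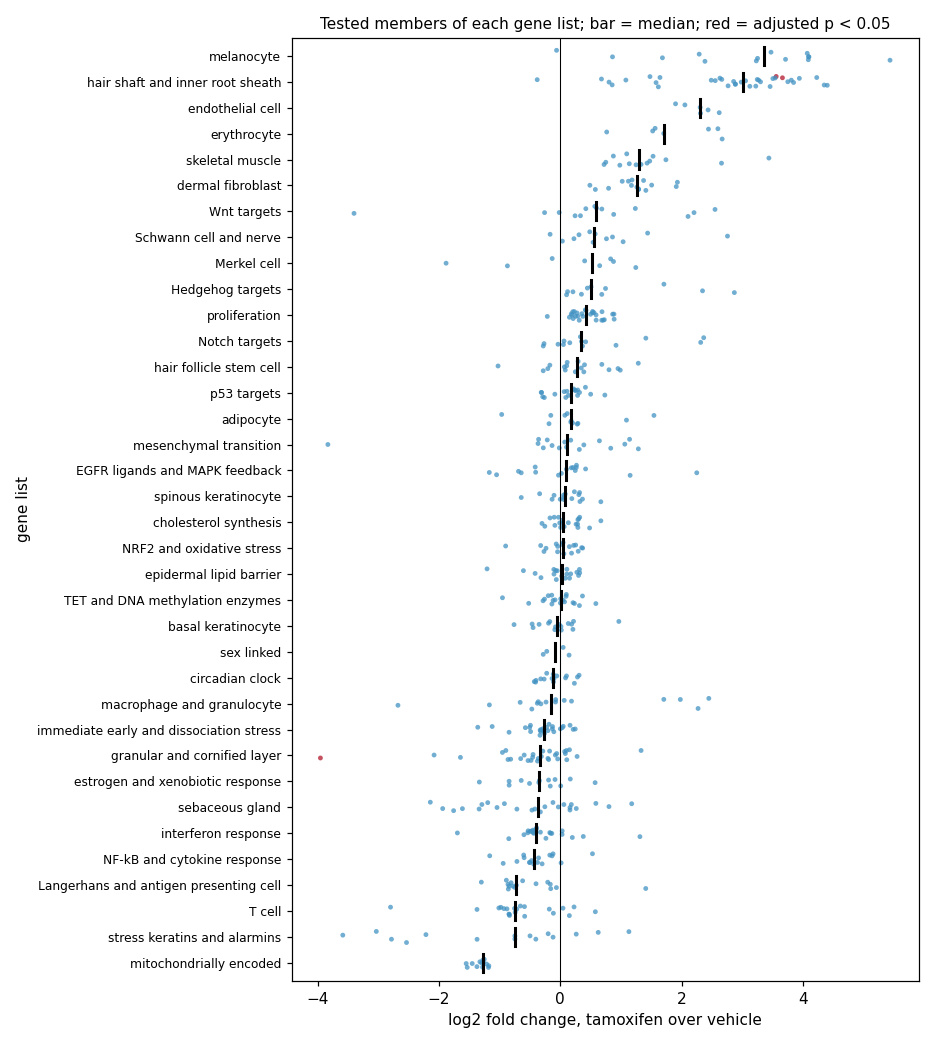
Log2 fold change, tamoxifen over vehicle, of the tested members of the 36 gene lists, ordered by their median (black bar); each point is 1 gene, red where its adjusted p over all genes was under 0.05. The medians run from 3.36 for melanocyte genes to -1.28 for mitochondrially encoded genes.

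In all, 21 of the 36 lists were called, 11 higher and 10 lower, with a preset correlation of 0.01 between genes. Values per library were not used here, so the correlation between genes of a list was not estimated. At 0.1 the calls numbered 13, 8 higher and 5 lower. The hair, melanocyte, endothelial and erythrocyte calls held up to a correlation of 0.6, the highest tried, and the mitochondrial call up to 0.46. Fibroblast and muscle calls held up to 0.25 and 0.22. Fold changes of independent genes would scatter by about their SE or more. Quartiles of mitochondrial genes were -1.37 and -1.25 (median SE 0.76), and of fibroblast genes 1.07 and 1.39 (0.86). Endothelial quartiles were 2.12 and 2.41 (0.83), and muscle quartiles 1.01 and 1.52 (1.06). The same held in other called lists, among them proliferation, with quartiles of 0.25 and 0.61 (0.68), and interferon, with -0.49 and -0.15 (0.66). NF-kB quartiles were -0.60 and -0.17 (0.63), and immediate early quartiles -0.45 and -0.11 (0.45). Genes of these lists thus varied together more than the presets allow, so their list p-values are too small. Of the lists that were not called, 6 had a median and a test of opposite sign.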

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

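The settings that filled in empty p-values, recentred fold changes, raised the correlation or used ranks were chosen after the data were seen. Calls of single genes depended on the threshold and the filter: 11 higher and 15 lower at an adjusted p under 0.10, 1 higher and 6 lower with no filter, and 1 higher and 7 lower after recentring, against 4 and 7 in the authors' deposited table. A minimum log2 fold change of 1 kept 4 and 7, the stricter filter (a mean of 40.5 normalised counts) gave 4 and 6 (Akr1d1 fell under the filter) and filled p-values 4 and 8 (Krt6b added). With no filter more genes were tested, and Krt71 and Krt27 (adjusted p = 0.0567), Cryba4 (0.0648) and Gm44829 lost their calls. Tet2 was not called in any of these, with adjusted p from 0.326 to 0.587.

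List calls numbered 20 or 21 in all settings but a correlation of 0.1, where they numbered 13, with 5 lower; that setting by construction widens the error of each list. In every setting 13 lists were called, 8 higher (hair, melanocyte, endothelial, erythrocyte, fibroblast, muscle, Wnt and Hedgehog) and 5 lower (stress, sebaceous, T cell, Langerhans and mitochondrial). None of these settings went above a correlation of 0.1. With higher presets, fibroblast, muscle and mitochondrial calls held only up to 0.25, 0.22 and 0.46. Wnt and sebaceous calls held up to 0.13, Hedgehog up to 0.15, Langerhans up to 0.11, and stress and T cell up to 0.21. For endothelial, fibroblast, muscle and mitochondrial genes the folds scattered less than their standard errors, so even 0.1 understates their correlation. The same held for other called lists, among them proliferation, interferon, NF-kB and immediate early genes. Calls were also lost for interferon (0.145) and for the estrogen and xenobiotic list (0.189) with no filter. The latter list also lost its call without shared members (0.0623). Calls were lost, too, for Schwann under the stricter filter (0.0719) and for Notch by ranks (0.0524). Follicle stem cell genes were called higher with no filter (0.0289). With no filter the interferon and follicle lists kept their 23 and 18 genes. Their mean fold change over SE also stayed, at -0.46 and 0.50, so only the genes compared against had changed. For the other lists the cause was not tested. Among uncalled lists the direction reversed under the stricter filter for spinous (0.757), cholesterol (0.816) and adipocyte genes (0.970). It reversed with no filter for lipid barrier (0.939), NRF2 (0.702) and Merkel genes (0.939), and without shared members for spinous genes (0.939). After recentring it reversed for Merkel genes (0.973), and by ranks for Merkel and macrophage genes (0.641 each). Under the stricter filter the spinous list kept its 16 genes and its mean fold change over SE, 0.13. With no filter the lipid barrier and NRF2 lists kept their 19 and 17 genes and their means, -0.07 and 0.04. There only the genes compared against had changed, and for the other reversals the cause was not tested. The Merkel list had too few genes under the stricter filter.

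Another normalization, other tests on counts, leaving out each mouse, an estimated correlation, the self-contained list test and other splits of the 6 libraries need values per library and were not run, so whether a single mouse decides a call is open. No paired analysis was possible because the groups share no replicate numbers. The depth of each library is unknown; at the median standard error of 0.49, changes under 2.04 on the log2 scale could not be called.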

Other observations

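Of the tests in this part, the tests of receptor genes and of genes by mean count had predictions written before their results were seen; the tests on hair genes and on genes without a p-value were chosen after the result was seen. The gene families in the first paragraphs were picked after their values were seen and share members with the called genes and the fixed lists, so they are given as values without a test. Of 37 tested keratin-associated protein genes, which fill the hair shaft matrix, 31 had a positive log2 fold change in the authors' deposited table, with a median of 2.27 and 21 at an unadjusted p under 0.05. All 7 tested Sprr2 genes, a small proline-rich family, were negative, with a median of -2.54 and 5 at an unadjusted p under 0.05 in the authors' deposited table. Of the 3 tested genes of the stefin and cystatin A cluster, 2 are the called Cstdc5 and Stfa3, and the other, Csta1, the most abundant at 10275 normalised counts, stood at -0.30 ± 0.59 in the authors' deposited table. Of the cluster members without an adjusted p, Csta3 stood at -4.63 ± 1.30, Cstdc6 at -4.27 ± 1.42, Stfa1 at -3.74 ± 1.05, Stfa2 at -2.84 ± 1.05 and Csta2 at -2.38 ± 1.25 in the authors' deposited table, and Cstdc2 and Cstdc7 had means under 3 normalised counts. Members of these families are near copies and share reads.

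In the Tmprss11 serine protease family, Tmprss11b stood at -5.52 ± 1.36 (adjusted p over all genes 0.0683) beside the called Tmprss11g, while the abundant Tmprss11f stood at -0.30 ± 0.69 and 2 of 5 tested members had an unadjusted p under 0.05 in the authors' deposited table. All 9 tested Ifi200 genes, an interferon-inducible family, were negative at a median of -0.67 in the authors' deposited table, 1 of them at an unadjusted p under 0.05. The 3 tested major urinary protein genes had a median of -1.35 and 0 at an unadjusted p under 0.05 in the authors' deposited table. Near the called Rnase2b in sequence, Ear2 stood at -0.71 ± 0.69 and Rnase2a at 0.08 ± 1.91 in the authors' deposited table. Ribosomal protein genes, 83 of them, had a median of 0.07 in the authors' deposited table, and 0 had an unadjusted p under 0.05.

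The rise of hair shaft, inner root sheath and melanocyte genes was weighed first. Deeper skin carried along with the tamoxifen epidermis stays open. Over measured genes, with or without a p-value, the median of 51 hair and melanocyte genes was 3.12. It lay 1.82 above that of 78 fibroblast, endothelial, muscle, adipocyte and Schwann genes, 1.31 (95% bootstrap interval 1.41 to 2.14). However, the medians of those 5 lists themselves ran from 0.19 to 2.48. The 2.48 is the endothelial median over 15 measured genes, 9 of them without a p-value, against 2.31 over the 6 tested. The fold from carry-over also depends on a level in the vehicle libraries that was not used here. A candidate explanation is a growing phase of the hair cycle in the tamoxifen mice. Wnt, Hedgehog and proliferation lists were all called higher, the largest cameraPR adjusted p being 0.00589. The proliferation call was lost at a correlation of 0.1 (adjusted p = 0.151), and its folds scattered less than their SEs. Follicle stem cell genes were not called (cameraPR adjusted p = 0.163). All these calls were known when the explanation was put forward, so they are no test of it. What deeper skin would do to these lists was not predicted, so they do not separate it from a growing phase. Whether a single library decides the rise cannot be told apart without values per library. Standard errors of the hair and melanocyte genes were 2.31 times those of genes matched on mean count. Yet 1 of 51 lacked a p-value against 9 of 15 endothelial genes (Fisher's exact p = 1.22e-06). That p-value treats genes as independent, which markers of 1 tissue may not be, and does not measure the spread between mice. A hair phase that differed between the mice by chance, the drug and the loss of Tet2 all stay open.

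Genes with few counts lay lower after tamoxifen: the 8471 genes with a mean of 1 to 10 normalised counts had a median log2 fold change of -0.97 (95% bootstrap interval -1.02 to -0.92) and 74.0% were negative, whereas the 6221 genes at 100 to 1000 had a median of 0.14, in the authors' deposited table. A candidate source is genomic DNA background in the vehicle libraries: of 197 olfactory and vomeronasal receptor genes with a mean under 10, which epidermis is taken not to transcribe, 185 were negative, and the median of their differences from genes matched on mean count was -0.562 (interval -0.586 to -0.541), while the medians themselves were -3.47 and -2.05. For the 13 such receptor genes with enough counts for an adjusted p, the difference from matched genes was not computed. Their own median was -0.10 in the authors' deposited table, with 8 negative and 5 positive. The explanation therefore rests on the genes with the fewest counts and stays open. Fitted folds of genes near 0 counts are no measure of size. Small counts in shallower tamoxifen libraries stay open, because the genes at 100 to 1000 lay at 0.136 (interval 0.128 to 0.145), neither near enough to 0 nor below it, and the depth of each library is unknown; no biological explanation was tested.

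The 191 genes without a p-value were mostly higher after tamoxifen, 160 against 31, with a median log2 fold change of 2.03 in the authors' deposited table. The authors' software empties a p-value where a library has an extreme count, so dermal, vascular and muscle tissue in part of the libraries is a candidate source: members of those 3 lists made up 18 of 53 where 0.669 would be expected from the 15124 genes with at least the lowest mean count of those without a p-value (odds ratio 44.3, Fisher's exact p = 1.30e-21). These lists were picked after their empty p-values were seen. Fisher's test, here and over all lists, treats genes as independent. Markers of 1 tissue may be flagged together by 1 library, so these p-values do not measure the spread between mice. Over all 36 lists, 4 were over-represented (Fisher's exact test, one-sided, Benjamini-Hochberg adjusted): endothelial (adjusted p = 1.14e-12), fibroblast (7.29e-05), muscle and stress keratins and alarmins (5.91e-04 each), and the 4 stress members without a p-value, among them Krt6b at -5.28 and Krt16 at -3.59 in the authors' deposited table, were lower. Deeper tissue therefore does not cover all of these genes, its part in the others stays open, and no biological explanation was tested.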
